A study of Mus musculus with 2 samples.

How the data were processed

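H3K36me3 ChIP-seq peaks were examined from 2 biological replicates of mouse hindbrain at embryonic day 13.5. Per the labels, tissue came from healthy B6NCrl embryos, males and females were pooled, and each replicate combined technical replicates. There were 4 peak lists, 1 called for each replicate, 1 for the pooled reads and 1 of replicated peaks. Per the deposited sample notes, the lists are in narrowPeak format on mm10, the list of replicate 2 was made from its alignment and a further file and that of replicate 1 from its alignment and 2 further files, and what these files hold is not stated. The replicated list names the other 3 lists as its source, and every row of it was found in the pooled list with the same coordinates. The rule by which peaks were kept is not stated. The aligner, the peak caller, their versions and the control used are not given in the sources used here.

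The deposited value of each peak is a signal, the enrichment value that the authors' caller gave it, and what it is relative to is not stated. It was used only to describe and rank peaks within a list and to set overlapping peaks side by side. The authors also deposited a −log10 p and a −log10 q per peak, which were used only to filter or rank. Every peak on the assembled chromosomes had an authors' −log10 p of at least 2.0. No read counts were part of these files, so depth is unknown, and a difference in the number of peaks between replicates may not be read as a difference in the mark. Columns that hold other samples were not met.

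Genes were taken from GENCODE release M21 on GRCm38, the assembly that mm10 names, and sequence from the RefSeq copy of GRCm38. No peak reached past the end of a chromosome of that assembly. Coordinates are 1-based. All computations were written in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9. Peaks on scaffolds outside the assembled chromosomes were left out of the comparisons. Peaks of a list were merged, and the covered percent of a gene is the share of bases from its annotated start to its end that lies under peaks. This measure rests on where the authors' caller drew peak edges. A broad mark called as narrow peaks is broken into pieces, with a median width of 386 bp in replicate 1, so cover understates the extent of weak domains.

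Peaks of the replicates were called shared with at least 1 bp of overlap. The background was 1000 circular shifts of a list within each chromosome, which keep widths and spacing, with a two-sided empirical p of at least 0.0020. The call per gene was one-sided, with a p of at least 0.000999. Features were protein-coding gene bodies, exons, introns, coding exons, 5' UTR, 3' UTR, windows of 1 kb on either side of protein-coding transcription starts, other genes and sequence outside genes. The profile used 10 equal parts of genes of at least 10 kb. Exon and intron cover left out the first exon and first intron and used marked genes with 3 or more exons. A gene was called marked at 10% cover or more in each replicate, a threshold of size without a p-value.

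For gene lists, 20 lists of symbols and 6 families defined by a pattern of names were fixed before the data were examined. The median over members of the mean cover of both replicates was set against 10000 random sets of protein-coding genes of the same size, matched in 20 bins of gene length and drawn with replacement. The permutation p was two-sided and adjusted by the Benjamini-Hochberg method over 26 lists. Genes in a list are not replicates, and these p-values compare a list with other genes in these samples. Where the central 95% of matched medians reaches down to 0 the test cannot find a list low, so a test of the number of marked members was added after seeing the data. The lists were neural progenitor, postmitotic neuron, proliferation, hindbrain and cerebellar patterning, forebrain patterning, posterior Hox, transmitter identity, axon guidance, morphogen signalling, oligodendrocyte and astrocyte, choroid plexus, endothelial and mural, microglia and immune, erythroid, meningeal mesenchyme, skeletal muscle, hepatocyte, housekeeping, H3K36 and DNA methylation machinery and imprinted genes. The families were olfactory receptors, vomeronasal receptors, numbered Zfp genes, clustered protocadherins, histones and ribosomal proteins. The housekeeping list and the ribosomal family share Rpl3, Rpl4 and Rps3.

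Genes to be named were also fixed before the data were examined. They were the 2 highest and the lowest member of each list by mean cover (the highest alone for families), the 15 genes of at least 5 kb with the highest cover, the 10 genes with the most bases under replicated peaks, the 5 genes of at least 5 kb with the largest difference between replicates in each direction, the 3 highest and 3 widest replicated peaks, and Setd2, Nsd1, En2, Egr2, Hoxb1, Hoxa2, Foxg1, Tubb3, Sox2, Atoh1 and Ptf1a. The marked members of the cell type lists, their overlapping genes, the genes without a peak in other lists and genes past the threshold in a single replicate were named after their values were seen. Alternatives left out each replicate, raised the −log10 q to 2 or 5, took the top 20000 peaks of each list, used the replicated list, changed the overlap to 50% of the shorter peak, the promoter window to 2 kb and the threshold to 5% or 20%, left out genes that overlap another gene, dropped the length matching, and called genes from the shifts.

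The steps were tested on simulated data with fixed seeds. Lists of scattered peaks were simulated with 200 seeded genes among 21938. All genes seeded at 20% and 50% cover were called marked, and 0 of those seeded at 5%. These calls follow from the threshold, which lies between 5% and 20%, and so check only the computation. Of genes without a seeded interval, 0.0552% were called. That rate holds for scattered peaks and is not a rate of false calls in the real lists. Circular shifts of the real lists, which keep widths and spacing, marked a mean of 2433 of 21938 genes. Of 200 random lists of 20 genes, 2% had a permutation p under 0.05 in the list test, and of 100 lists with 12 members covered at 50%, all did. With 12 of 20 members seeded, the median of such a list lies near 50% by construction, so the second rate checks only the computation. Both rates hold for scattered simulated peaks and not for the cover of the real lists. Of 50 pairs of independent lists of 5000 peaks, 4% had a shift p under 0.05, and a pair made to share 60% of peaks was measured at 60.0%.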

Results

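The series measured H3K36me3, the trimethyl mark on histone H3 that lies over the bodies of transcribed genes, by ChIP-seq in mouse hindbrain at embryonic day 13.5. There were 2 biological replicates of a single group, each from embryos of both sexes pooled, and no second tissue, age or control sample was analysed here. Each replicate came with its own peak list, and a pooled list and a list of replicated peaks covered both. The design therefore allowed the replicates to be compared with each other, and the place of the mark in the mm10 genome to be described. The files held peaks and no read counts, so the sequencing depth of each replicate is unknown and no counting interval was computed.

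The question of the first comparison was how far the replicates marked the same sequence. Replicate 1 had 186110 peaks and replicate 2 had 168659. After merging on the assembled chromosomes they covered 129 Mb (4.74% of the genome) and 104 Mb (3.81%), so replicate 1 covered 1.24 times as many bases. Of the peaks of replicate 1, 66.9% shared at least 1 bp with a peak of replicate 2, against a mean of 6.79% when the list was shifted around each chromosome. Of the peaks of replicate 2, 86.3% were shared, against 7.94%. The base Jaccard index was 0.621, against 0.0250 for shifted lists. In each of the 3 measures the two-sided permutation p was 0.0020, the smallest that 1000 shifts can give. Peaks without a partner were lower in the authors' enrichment value. The median was 2.80 for unshared and 3.71 for shared peaks of replicate 1, and 2.81 and 3.42 in replicate 2. Across 124537 pairs of overlapping peaks, which are not independent, the heights had a Spearman correlation of 0.548 and a Pearson correlation of 0.59 on the log2 scale. Over 12634 pairs among the top 20000 peaks of each list, a setting added for heights after seeing the data, the Spearman correlation was 0.339 and the Pearson correlation 0.482 on the log2 scale. That setting narrows the range of heights, which by itself can lower a correlation. The lower values may thus not be read as poorer agreement of the highest peaks. Cover per gene had a Spearman correlation of 0.972 across 21938 protein-coding genes, which are not independent either.

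The pooled list held 194767 peaks, of which the authors kept 131304 as replicated. On the assembled chromosomes this was 67.4% of the pooled peaks. Kept peaks had a median authors' enrichment value of 3.28 and a median width of 605 bp, against 2.29 and 225 bp for the others. Both replicates' own lists touched 78.7% of the kept peaks and 0.787% of the others. The 3 replicated peaks with the highest enrichment values lay in genes for zinc finger proteins. They were at chromosome 9, 22276273 to 22281182, in Zfp810 (authors' enrichment value 19.2), at chromosome 7, 30160630 to 30164351, in Zfp146 (18.96), and at chromosome 7, 12807289 to 12811680, in Zfp329 (17.8). Each reached into an annotated 3' UTR, and exons made up 53.8%, 52.7% and 99.7% of their bases. The widest replicated peak spanned 36273 bp of Trrap, which encodes a scaffold of histone acetyltransferase complexes (chromosome 5, 144820852 to 144857124). The next widest lay in Kmt2d, a histone H3 methyltransferase gene, with 33914 bp (chromosome 15, 98833036 to 98866949), and in Dync1h1, the cytoplasmic dynein heavy chain gene, with 32581 bp (chromosome 12, 110612376 to 110644956).

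The mark lay inside protein-coding genes and away from their starts. Protein-coding gene bodies took up 38.2% of the genome and held 93.8% ± 0.268 of the peak bases (SD, n = 2), which was 2.29-fold the mean of 1000 shifted lists. Coding exons were 7.46-fold ± 0.509 over shifted lists, 3' UTRs 5.66-fold ± 0.142 and introns 1.99-fold ± 0.0200 (SD, n = 2 for each). Introns still held most of the bases, at 75.4% ± 0.682 (SD, n = 2). The window of 1 kb on either side of a protein-coding transcription start held 0.427% ± 0.00153 of the peak bases, 0.257-fold of the shifted mean (0.438-fold with 2 kb on either side), and sequence outside any annotated gene held 5.09% ± 0.206, 0.0972-fold (SD, n = 2). The 5' UTR stood closer to the shifted lists, at 0.863-fold ± 0.0217 (SD, n = 2). The two-sided permutation p, adjusted by the Benjamini-Hochberg method over 9 features, was at most 0.00225 in each replicate for every feature but the 5' UTR, where it was at most 0.026.

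**Figure D1:**
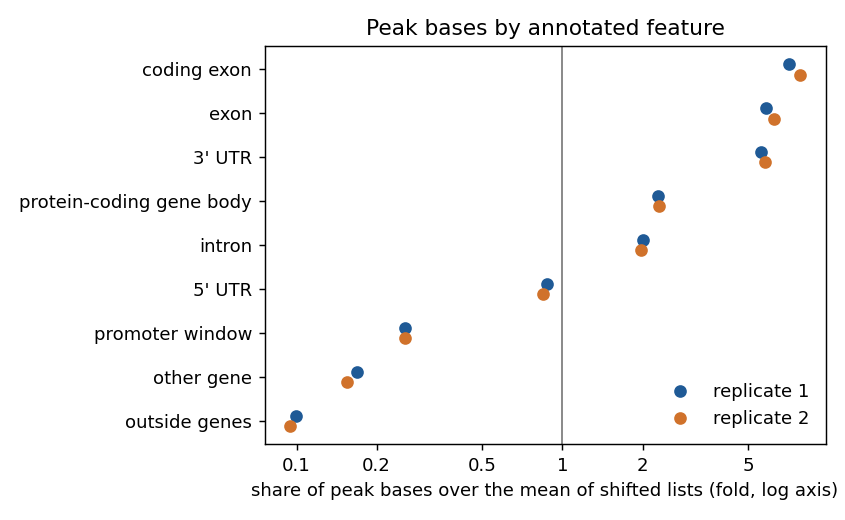
Share of peak bases in each annotated feature divided by its mean over 1000 circular shifts of the list (horizontal log axis), with a point per replicate and a grey line at 1. Coding exons stand highest, at a mean of 7.46-fold, and sequence outside genes lowest, at 0.0972-fold.

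Within genes the mark rose towards the 3' end. Over 14164 protein-coding genes of at least 10 kb, the mean covered percent went from 3.27% in the 5' part of 10 equal parts to 30.9% in the 3' part in replicate 1, and from 2.41% to 26.4% in replicate 2. The ratio of the last 5 parts to the first 5 was 2.01 ± 0.0750 (SD, n = 2), and among genes with any cover 83.9% in replicate 1 and 83.8% in replicate 2 had more cover in the last 5 parts. Among 7638 marked genes with at least 3 exons, exons after the first were covered at 69.2% and introns after the first at 47.9% in replicate 1. In replicate 2 the values were 61.7% and 39.6%. The ratio of exon to intron cover was 1.502 ± 0.0807 (SD, n = 2). Bases were summed over all these genes before dividing, so long genes weigh more in the intron share than in the exon share. The ratio thus mixes differences between genes with those between exons and introns of a gene. The profile and the exon and intron values are descriptions over genes, which are not replicates, and carry no p-value.

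**Figure D2:**
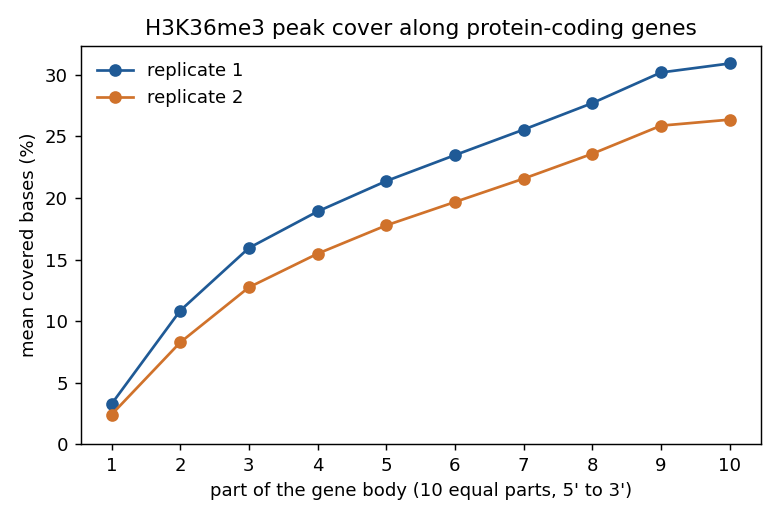
Mean percent of bases covered by peaks (vertical axis) in each of 10 equal parts of the gene body from 5' to 3' (horizontal axis), over 14164 protein-coding genes of at least 10 kb, with a line per replicate. Both lines rise along the gene, to 30.9% in replicate 1 and 26.4% in replicate 2.

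A gene was called marked when peaks covered at least 10% of its body in each replicate. By this rule 7968 of 21938 protein-coding genes (36.3%) were marked, against a mean of 2433 and a highest count of 2866 over 1000 circular shifts (two-sided permutation p = 0.0020, the smallest the shifts can give). No peak of either replicate touched 9713 genes (44.3%). Marked genes had a median cover of 44.9% in replicate 1 and 37.2% in replicate 2, and 93.3% of them were covered further in replicate 1. The most fully covered genes of at least 5 kb included Gigyf1 (94.96% ± 1.42, chromosome 5, 137518548 to 137527935), Trrap (91.3% ± 1.76), Ints1 (89.9% ± 1.57), which encodes an Integrator subunit, Rnf40 (89.8% ± 2.999), a histone H2B ubiquitin ligase gene, Polr3a (88.8% ± 1.70), the largest subunit of RNA polymerase III, and Sf3a1 (88.8% ± 3.54), a splicing factor gene (SD, n = 2 for each). Kmt2b, another H3 methyltransferase gene, had 88.2% ± 1.17 and the polarity gene Scrib 89.6% ± 0.0375 (SD, n = 2). Prss53 (96.1% ± 5.58) and Pla2g4b (93.7% ± 3.49) ranked among these as well. Several of these genes share their bases with another model: Prss53 and Pla2g4b with the predicted genes Gm21974 and Gm28042, covered at 67.3% and 80.7%, Gigyf1 wholly with Epo (26.6%), and Rnf40 over 5485 bases with the antisense gene Gm44759. Among genes with an established symbol, Fgfr2, Syne2, Vps13d, Wdfy3, Macf1 and Kalrn held the most bases of replicated peaks, with 147302 bases in Syne2 and 143180 in Vps13d. The annotated Fgfr2 model spanned 2961 kb, was covered at 6.65% ± 1.30 (SD, n = 2) and overlapped other covered genes, among them Abraxas2 (61.1% ± 0.776) and Bub3 (52.4% ± 5.41) (SD, n = 2), so its bases were not those of Fgfr2 alone. Peaks carry no strand, and 57.3% of marked genes overlapped another annotated gene, against 46.6% of all protein-coding genes. A call per gene against its own 1000 circular shifts, Benjamini-Hochberg adjusted, gave 0 genes (smallest adjusted p 0.184), while 4431 genes had an unadjusted permutation p under 0.05 in both replicates. The smallest one-sided permutation p that the shifts can give, 0.000999, was reached by 94 genes in replicate 1 and 119 in replicate 2. Fewer than 439 genes at that p in a replicate could not pass the adjustment, so the number of shifts limits the call for them. All other genes were equalled or exceeded by some shift, so for them the background of shifted cover limits the call too. Whether more shifts would call genes was not tested.

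Genes used by every cell and genes of the chromatin machinery carried the mark widely. Of 20 housekeeping genes 17 were marked, with a median cover of 51.0% in replicate 1 and 44.9% in replicate 2, led by the translation genes Eif4g2 (82.6% ± 0.639, chromosome 7, 111067750 to 111083030) and Eef2 (81.6% ± 4.01), with Ubc lowest at 5.83% ± 0.534 (SD, n = 2). Of 83 ribosomal protein genes 64 were marked, with medians of 43.6% and 38.6% and Rps3 highest at 75.6% ± 0.908 (SD, n = 2). Of 18 genes for enzymes and readers of H3K36 and DNA methylation 16 were marked, with medians of 47.4% and 37.4%. They included the demethylase gene Kdm4a (87.7% ± 2.83, chromosome 4, 118136957 to 118180043), Brpf1 (71.8% ± 3.45), Nsd1 (51.7% ± 9.81) and Setd2, which encodes the main H3K36 trimethylase (40.2% ± 4.44, SD, n = 2), while Dnmt3b was lowest at 10.1% ± 2.97 (SD, n = 2). Against 10000 random sets matched on gene length, the two-sided permutation p, Benjamini-Hochberg adjusted over 26 lists, was 0.0052 for housekeeping genes, 0.0026 for ribosomal protein genes and 0.0035 for the H3K36 and DNA methylation genes. Among members that overlap no other gene the call was kept for ribosomal protein genes (35 members, median 33.9%, adjusted permutation p = 0.0025). It was lost for housekeeping genes (9 members, 45.4%, 0.098) and for the H3K36 and DNA methylation genes (3 members, 36.01%, 0.67), with fewer members and medians that stayed high.

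Genes of postmitotic neurons and of 2 large gene families lay above length-matched sets. Of 20 genes of postmitotic neurons 13 were marked and all had a peak in both replicates, with medians of 16.8% and 12.4% and an adjusted permutation p of 0.037. Ina, which encodes the neurofilament protein alpha-internexin, had 49.4% ± 0.526 (chromosome 19, 47014698 to 47025327), the RNA-binding protein gene Elavl3 45.9% ± 2.47 and Tubb3, a neuronal tubulin gene inside the predicted gene Gm20388, 39.8% ± 1.52, while the synaptic gene Nrxn1, over 1 Mb long, had 0.488% ± 0.123 (SD, n = 2 for each). The median over both replicates was 14.6%, against 1.78% in random sets. This call was lost without length matching (adjusted permutation p = 0.52, random sets at 1.68%) and with GC matching added after seeing the data (0.053, 2.30%). It was also lost among the 4 members that overlap no other gene (0.67), whose median was 21.6% against 3.83%. Of 391 numbered Zfp genes 279 were marked (medians 35.7% and 29.97%, adjusted permutation p = 0.0026), with Zfp869 at 91.9% ± 6.39 (SD, n = 2). Of 57 clustered protocadherin genes 27 were marked (adjusted permutation p = 0.0052), with Pcdhga3 at 52.8% ± 3.18 (SD, n = 2), but members of this family overlap each other and share peaks, and the call was lost without length matching (0.18, with a median of 11.4% against 1.14% in random sets and 0.882% in matched ones).

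Several other lists did not stand apart from length-matched sets. Of 18 neural progenitor genes 6 were marked (adjusted permutation p = 0.90), with the RNA-binding protein gene Msi1 at 60.2% ± 3.36 (chromosome 5, 115429599 to 115455698) and Dbi at 42.3% ± 0.671 (SD, n = 2), and Sox2 and Sox9 without a peak. Of 18 proliferation genes 9 were marked (0.90), among them the replication helicase genes Mcm4 (64.3% ± 7.03) and Mcm5 (58.6% ± 9.67), while Ccnd2 had 0.666% ± 0.942 (SD, n = 2). Of 20 axon guidance genes 8 were marked (0.12), from Plxna1, a semaphorin receptor gene, at 77.6% ± 4.19 and Cntn2 at 31.6% ± 5.24 to Sema3a at 0.0946% ± 0.0763 (SD, n = 2). Of 21 genes of morphogen signalling 6 were marked (1.0), with Axin2 at 43.5% ± 6.21 and the hedgehog receptor gene Ptch1 at 42.5% ± 3.49 (SD, n = 2), and Wnt1 without a peak. Of 16 transmitter genes 3 were marked (0.47), with Gad1 at 23.3% ± 9.19 and Gad2 at 20.4% ± 4.76, both for enzymes that make GABA (SD, n = 2), and Tph2 without a peak. Of 18 imprinted genes 8 were marked (0.73), with Nnat, which lies wholly inside Blcap (covered at 48.0% ± 3.30), at 77.0% ± 11.9 and Igf2r at 57.2% ± 3.796 (SD, n = 2) and no peak in Ndn. Each value in parentheses after a count is an adjusted permutation p.

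Genes that set regional identity were rarely marked. Of 30 hindbrain and cerebellar patterning genes 2 were marked, Meis1 (13.5% ± 3.41, chromosome 11, 18879817 to 19018985) and Hoxb2 (11.9% ± 0.446, chromosome 11, 96350525 to 96354012) (SD, n = 2), and 11 had a peak in both replicates. Meis1 and Hoxb2 each overlap another annotated gene, so their cover may also be that of an overlapping gene. Zic1 (11.4%) and Zic2 (10.5%) passed the threshold of 10% in replicate 1 only, and Lhx1 (12.9%) and Lhx5 (10.8%) in replicate 2 only. No peak lay in En2, Egr2, Hoxb1, Hoxa2, Atoh1 or Ptf1a. Of 20 forebrain patterning genes 0 were marked, Foxg1 had no peak and Lhx2 was highest at 0.387% ± 0.548 (SD, n = 2). No posterior Hox gene had a peak in either replicate (18 members). The planned test of medians gave an adjusted permutation p of 1.0 for each, and could not find such lists low because the central 95% of matched medians reached down to 0. A test of the number of marked members, added after seeing the data, put all 3 lists below length-matched sets, whose means were 9.08, 6.74 and 4.63 marked genes, with adjusted permutation p of 0.0057, 0.0026 and 0.013. Matched sets were drawn gene by gene from all chromosomes, while some members, such as Hox genes, lie next to each other. Neighbours may not be independent, so these p-values may be too small.

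Markers of other cell types were also rarely marked. In 4 lists no gene was marked: endothelial and mural (14 genes, matched mean 5.22), erythroid (14, 4.37), meningeal mesenchyme (12, 4.64) and skeletal muscle (14, 4.51), with adjusted permutation p of 0.0065, 0.012, 0.0080 and 0.012 in the added test of counts. The planned test of medians, whose matched sets again reached down to 0, gave 0.26, 1.0, 0.90 and 0.73. Pdgfrb of the endothelial and mural list (10.2%) and Epor of the erythroid list (12.6%) passed the threshold of 10% in replicate 1 only. The added test gave 0.015 for oligodendrocyte and astrocyte genes (1 of 14 marked), 0.079 for choroid plexus (1 of 11) and 0.22 for microglia and immune genes (2 of 14), where the planned permutation test gave adjusted p of 0.71, 0.73 and 0.90. The marked members were Mog (16.5% ± 1.48), Kcnj13 (28.9% ± 3.46), Cx3cr1 (16.3% ± 1.44) and Fcer1g (20.0% ± 0.619) (SD, n = 2). Of these only Fcer1g overlaps no other annotated gene, so the cover of Mog may also be that of an overlapping gene. Kcnj13 lies wholly inside Gigyf2, covered at 37.1% ± 8.41, Alas2 inside Apex2, covered at 10.1% ± 1.63, and the annotated Cx3cr1 model overlaps Wdr48, covered at 67.0% ± 7.22 (SD, n = 2). Pdgfrb (7.34% ± 4.05), Alas2 (8.96% ± 1.47), Ttn (5.43% ± 1.17) and Prrx1 (0.257% ± 0.364) were the highest of the endothelial, erythroid, muscle and mesenchyme lists (SD, n = 2). Of lists not known for this tissue, hepatocyte genes (14), olfactory receptor genes (1093) and vomeronasal receptor genes (327) had 0 marked members, with matched means of 5.64, 320 and 115 and adjusted permutation p of 0.0035, 0.000867 and 0.000867 in the added test and 0.88, 1.0 and 1.0 in the planned one. The receptor families hold paralogs, where reads may be shared or unmappable, so a lack of peaks there may not be a lack of the mark. Whether reads could be placed in these genes was not tested. Of 79 genes in the histone family 3 were marked (adjusted permutation p = 0.13 in the added test, 1.0 in the planned one).

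**Figure D3:**
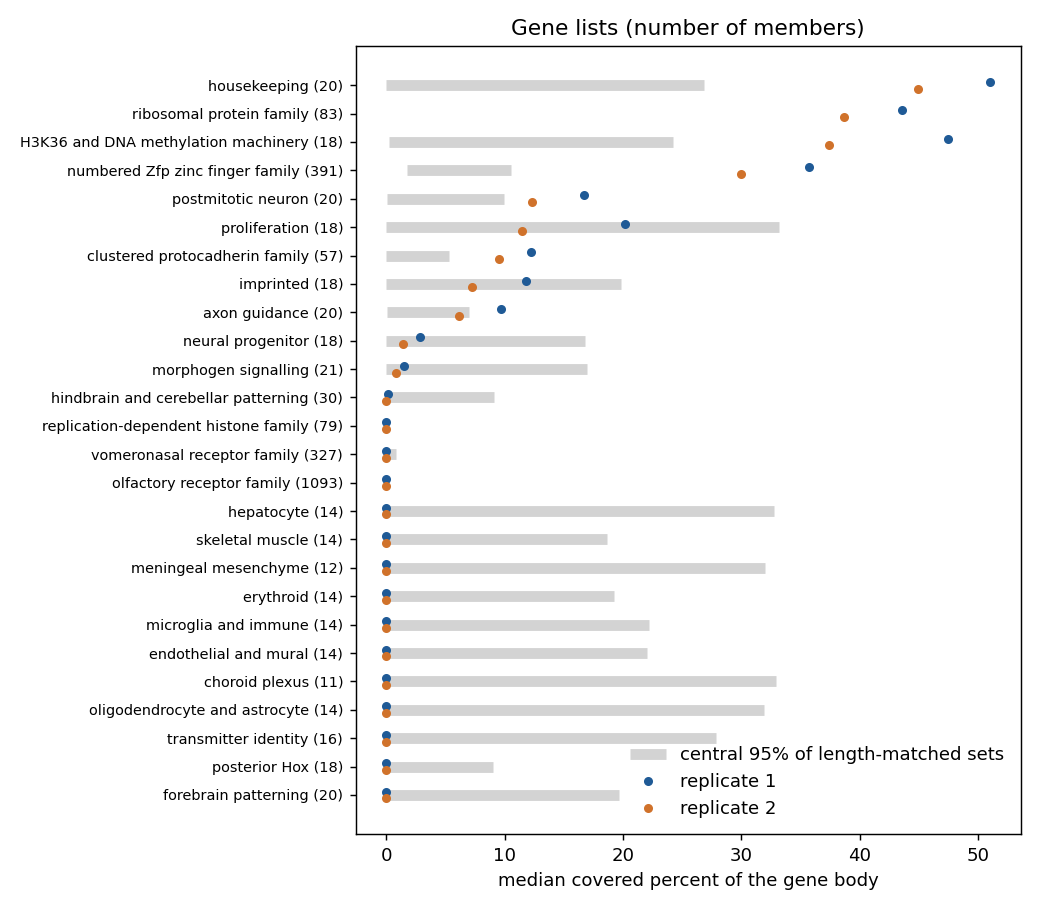
Median percent of the gene body covered by peaks (horizontal axis) for each of 26 gene lists, with a point per replicate and a grey bar for the central 95% of 10000 length-matched random sets. Housekeeping genes stand highest, at 51.0% and 44.9%, and lists at 0 lie at the lower end of their bars.

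The last comparison set chromosomes side by side. On autosomes the share of protein-coding genes marked ranged from 28.7% on chromosome 14 to 47.4% on chromosome 8. Of 948 X-linked genes 102 were marked (10.8%), against 7866 of 20807 autosomal genes (37.8%). Taken per replicate, 14.8% of X-linked and 41.7% of autosomal genes passed 10% in replicate 1, and 11.3% and 38.0% in replicate 2, a ratio of 0.326 ± 0.0408 (SD, n = 2). Of 183 Y-linked genes 0 were marked. With peaks limited to an authors' −log10 q of at least 5, a setting chosen after seeing the data, the X to autosome ratio was 0.187.

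**Figure D4:**
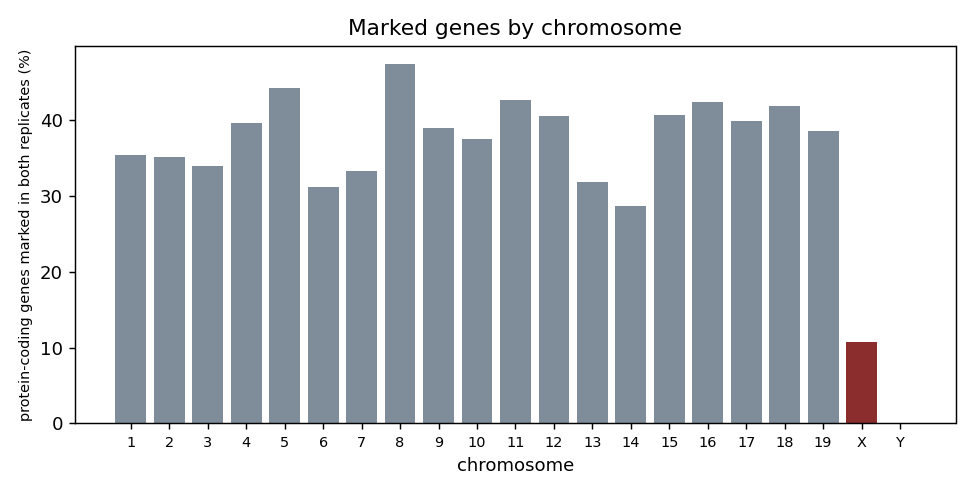
Percent of protein-coding genes marked in both replicates (vertical axis) on each chromosome (horizontal axis), with X in red. Autosomes lie between 28.7% and 47.4%, X at 10.8% and Y at 0.

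The 10 genes of at least 5 kb whose cover differed most between replicates, 5 in each direction, were 5.01 to 22.7 kb long. The largest excess in replicate 1 was in Nop16, a nucleolar protein gene (70.0% against 38.1%, chromosome 13, 54584185 to 54590090), followed by Trmt61a (46.0% against 14.8%), Atp5g1 (48.7% against 17.9%), Rab23 (72.2% against 41.4%) and Chtf18 (31.5% against 2.34%). The largest excess in replicate 2 was in Tmem79 (24.0% against 5.02%), followed by Trmt10c (42.7% against 24.5%), Zbed6 (40.04% against 23.0%), Glmp (42.8% against 29.3%) and Resp18 (14.4% against 2.90%). Tmem79 and Glmp overlap by 2659 bases, and Zbed6 lies wholly inside Zc3h11a. With the top 20000 peaks of each list 8 of the 10 differences moved by more than the spread, that of Atp5g1 did not, and that of Rab23 turned to −6.84 points. With a −log10 q of at least 5, chosen after seeing the data, that of Trmt10c turned to 12.3 points (replicate 1 minus replicate 2 in both cases). With a single value per gene and replicate, these differences were not tested.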

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

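Peaks on scaffolds that are not placed in the assembled chromosomes were outside every comparison above, and are listed here because they are a signal in data not otherwise reported on. The list of replicate 1 held 56 such peaks, that of replicate 2 held 43, the pooled list 75 and the replicated list 35. They lay on 12 scaffolds in each replicate's list, covered 23189 bases in replicate 1 and 16855 bases in replicate 2, and had median authors' enrichment values of 2.34 and 2.53, against 3.27 on the assembled chromosomes in both lists. No peak lay on the mitochondrial genome. Genes on these scaffolds were not analysed here.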

How the results depend on the processing

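The settings with a −log10 q of at least 5, internal exons only, GC matching, the count of marked members, the top 20000 peaks for heights and the removal of predicted genes were chosen after seeing the data. Of 727 values under alternatives, 635 kept their direction and their side of the threshold or moved by less than the spread. All overlap values (57.5% to 90.1% of peaks, Jaccard index 0.514 to 0.617) and all feature folds did so. Where the spread was the rule, a value without 1 of the 2 replicates always lies within their SD and could not count as moved. This holds for the profile, exon to intron and X to autosome ratios and for the covered percent of 101 named genes. Their stability without a replicate was thus fixed in advance. For the values below the cause was not tested unless stated. The height correlation was 0.554 with 50% overlap, 0.535 at −log10 q of 2, 0.440 at 5 and 0.339 with the top 20000 peaks. At 5 the profile ratio was 2.21, the exon to intron ratio 1.68 and the X to autosome ratio 0.187, and with internal exons only the exon to intron ratio was 1.69. Marked genes numbered 3404 without genes that overlap another and 3499 with the top 20000 peaks, both by construction subsets of fewer genes or peaks. They numbered 0 in the shift test, which the number of shifts limits only for genes at the smallest p. Without a replicate the count was 8018 to 8807. Among genes that overlap no other, medians were 21.6% for postmitotic neuron, 45.4% for housekeeping and 36.01% for H3K36 and DNA methylation genes, no longer past the threshold with fewer members. Without length matching, postmitotic neuron genes (14.6%) and protocadherins (11.4%) also lost it and olfactory receptors (0) passed it, and with GC matching postmitotic neuron genes (14.6%) lost it. The count of marked members reversed hindbrain patterning (2) and brought past the threshold forebrain patterning, posterior Hox, endothelial, erythroid, mesenchyme, muscle, hepatocyte, olfactory and vomeronasal genes (0 each) and oligodendrocyte genes (1). Among named genes, 61 of 434 values moved, 45 of them falls at −log10 q of 5, and the replicate difference reversed for Rab23 (−6.84 points, top 20000 peaks) and Trmt10c (12.3 points, −log10 q of 5). Depth is unknown, so how many unmarked genes lie below detection was not tested. With a −log10 q of at least 5 the count of marked genes was 6275.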

Other observations

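Matching on GC content, the removal of predicted genes and receptor families, the test of Zfp genes among marked genes and the tests of patterning genes by length and without marked genes were chosen after seeing the data, and so was the comparison of noncoding genes, whose list was fixed before their values were computed.

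Some long noncoding genes carried the mark as widely as housekeeping genes. On chromosome 12, the imprinted noncoding genes Meg3 (61.3% ± 13.9 of the body covered, 109541001 to 109571726), Mirg (61.8% ± 7.54, 109729764 to 109749460) and Rian (29.0% ± 2.85) were marked in both replicates (SD, n = 2). So were Malat1 (42.1% ± 4.51), Miat (39.8% ± 3.72), Gas5, a host gene of small nucleolar RNAs (35.2% ± 8.36), Rmst (27.0% ± 6.19) and Peg13 (35.5% ± 31.8, 58.0% in replicate 1 and 13.04% in replicate 2) (SD, n = 2). Peg13 is annotated as sense intronic, within an intron of another gene, so its cover cannot be told from that of its host. Neat1, next to Malat1 on chromosome 19, had 0.433% ± 0.613, Xist 0.577% ± 0.816, Sox2ot 0.149% ± 0.00318, Kcnq1ot1 5.43% ± 3.70, Airn 4.58% ± 0.662 and Snhg14 2.47% ± 0.578 (SD, n = 2), and H19, Hotair and Dlx6os1 had no peak. Of 5358 lincRNA genes that overlap no protein-coding gene 77 were marked (1.44%).

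All 21 protocadherin gamma genes were marked, with a median cover of 44.7%, against 5 of 14 alpha genes and 1 of 22 beta genes (Pcdhb22). Gamma genes overlap each other and so share peaks, and no member of the whole family was free of overlap with another annotated gene. The alpha count also holds repeated entries of the symbol Pcdha11. These counts are thus not independent, and the contrast between the groups may rest on a few shared peaks. Of the histone family, 67 genes with Hist symbols, whose transcripts mostly end without a poly(A) tail, had no peak in either replicate. Of the 12 other members 3 were marked, H2afv (53.1% ± 2.46), H2afy2 (48.8% ± 4.91) and H2afy (46.5% ± 8.40) (SD, n = 2), which encode histone variants. The variant genes H2afx and H2afj had no peak, and H2afz had 0.185% ± 0.261 (SD, n = 2). The family had a median gene length of 586 bp, and 16.7% of all protein-coding genes under 5 kb were marked. Of 102985 windows of 10 kb lying at least 5 kb from any gene, 4 were covered at 30% or more in both replicates. Each lay on the 3' side of its nearest protein-coding gene, 2 of them beyond Elavl2 at chromosome 4, 91210001 to 91230000, 1 beyond Rcn2 on chromosome 9 and 1 on chromosome 5, 57.4 kb beyond BC005561 and 25.8 kb beyond the marked lincRNA gene D930016D06Rik (58.5% ± 5.26, SD, n = 2).

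X-linked genes were marked less often than autosomal genes (10.8% against 37.8%). Autosomal genes matched on length and GC content were marked at 29.8% on average (26.1% to 34.1% over 1000 sets), and with predicted genes and receptor families left out the ratio was 0.332, which argues against gene length and GC content and against such families as the whole cause. Peaks in marked X-linked genes had lower median enrichment values than those in marked autosomal genes, by a mean difference of −0.241 (3.27 against 3.45 in replicate 1, 3.12 against 3.42 in replicate 2). Weaker peaks from a lower dose of X DNA stay open, but any other cause of lower peaks on X would give the same difference. Of X-linked genes 28.7% had any peak in both replicates, against 52.7% of autosomal genes. No biological explanation was tested, and pooled sexes leave the dose of X unknown.

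The highest peaks gathered in numbered Zfp genes, which held 51 of the 100 highest peaks in each replicate but 1.84% and 1.92% of all peaks. Reads shared between identical copies would need many repeated words, but 5.35% of the 31-base words in Zfp peaks occurred elsewhere in the genome, against 3.31% in other peaks. The medians per peak were 1.59% and 0.158%. These values argue against identical copies as the main source. Only exact words of the reference in called peaks were counted, so copies that differ or are missing from the reference stay open. Over all Zfp genes, with genes without a replicated peak centred in them at 0, the median of the highest enrichment values was 6.13. That of 1000 sets of other genes matched on length and GC content reached 3.70 at most, a gap that also reflects how many Zfp genes were marked. Some genes covered by peaks are at 0 too, since no replicated peak has its centre in them. Among marked genes only the gap was smaller but remained, with 6.97 against at most 5.96 over 1000 matched sets, which argues against gene length and GC content as the whole cause. The background that the authors' caller used, which is not stated, was not tested, and no biological explanation was tested.

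Hindbrain patterning genes were rarely marked, with 2 of 30. Short genes alone would put the count within the central 95% of length-matched sets, whose lower bound was 5, and GC content together with length within a range whose lower bound was 7, so both are argued against for genes marked in both replicates. The sets were drawn gene by gene, so these ranges may be too narrow for a list with neighbouring Hox genes. Zic1 and Zic2 passed 10% in replicate 1 only and Lhx1 and Lhx5 in replicate 2 only. Counts of a single replicate were not set against matched sets. The mark in part of the cells, below the 10% threshold, stays open. Without the 2 marked genes, 9 of 28 hindbrain and 1 of 20 forebrain genes had a peak in both replicates (Fisher's exact test, two-sided p = 0.031, and 0.016 with them at 11 of 30), but the lists differ in gene length. Among genes over 20 kb the counts were 8 of 11 and 1 of 3 (Fisher's exact test, two-sided p = 0.51), and among unmarked genes up to 20 kb they were 2 of 18 and 0 of 17 (p = 0.49), too few to decide.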
